A study of Caenorhabditis elegans with 8 samples.

How the data were processed

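RNA from whole adult Caenorhabditis elegans of the N2 wild-type strain was measured in 8 libraries, 4 from worms fed bacteria with the empty feeding vector (control) and 4 from worms fed bacteria making spk-1 double-stranded RNA (spk-1(RNAi)). Per the labels' protocols, larvae of the fourth stage grown at 20 °C were fed for 24 h at 25 °C, at least 100 adults were collected per condition, and polyadenylated RNA was made into libraries that mark strand by dUTP. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The submitters' processing notes name TopHat 1.4.1, Bowtie2 2.0.0 and the genome build ce10, without their roles. The read counter, the annotation and the rule by which introns were listed are not given in the sources used here.

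Per the file headers, the authors' longer junction table gives read counts over introns, not normalized, for each library. It listed 20349 introns, of which 25 stood on both strands. The copies of these 25 were equal in all libraries but control replicate 1, where 17 differed, and 1 copy was kept, which left 20324 introns. Every intron had more than 20 reads in every control library, with minima of 21 to 22, while the lowest count in an spk-1(RNAi) library was 1, a difference found by testing the values. An intron used mainly after spk-1(RNAi) would therefore be missing from the table, and retained introns are not measured by it. The deposited p-value of each intron was recomputed as a one-sample, 2-sided Student test of the 4 normalized ratios against 1, within 1% for 20347 introns and not for 2. Per the file headers, those ratios divide the reads of each numbered pair and are scaled to total read number. The headings name control first, but the values equal spk-1(RNAi) over control, and that direction is used. The deposited shorter table holds the 258 introns with p-values under 0.01. The authors' deposited exon-bin table gives p-values and adjusted p-values from DEXSeq and a normalized mean signal per bin, per the file headers and the name of the table. It gives no direction of change, and no DEXSeq version is given in the sources used here.

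Libraries were assigned to groups by their labels and columns by their headings. The same spk-1(RNAi) heading stood over 2 columns. Their numbers, 1 and 4, were taken from the authors' ratio headings, because the ratios of that number equalled the quotient of the column's reads and those of the same-numbered control in 100% of introns, compared in the digits printed, and those of other columns in at most 4.81%. This step matters wherever replicate numbers are used, as a block, in ratios and counts by pair, in subsets of pairs and in naming single libraries, and an alternative with pairs 2 and 3 alone, whose headings are unambiguous, stands beside it. No column of per-sample values was left unused (0 columns). Gene names were taken from the authors' table by sequence name, and 5707 of 5762 names matched a symbol in the reference annotation, of another build. Reference annotation also gave the gene strand by which 1 copy of each doubly listed intron was kept. Of 20026 intron lengths compared with it, 99% matched with listed starts counted from 0. A further 160 introns carried no gene. Coordinates are those of the authors' tables in ce10, counted from 1.

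Library totals ran from 1821717 to 47299659 junction reads. Introns that share a donor or an acceptor were compared at 150 shared sites (112 donors and 38 acceptors, 289 introns). Usage was tested with diffSpliceDGE on a quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3, with TMM scaling, group as the only term and Benjamini-Hochberg adjustment at 0.05. The share of the longest intron at each site was given in percent as the mean ± SD of 4 libraries. Sites were grouped as skipped exons, where the longer intron spans a listed pair of introns, alternative donors and alternative acceptors. All other shared acceptors were counted as alternative donors and all other shared donors as alternative acceptors, without a check against annotated transcripts. Junction reads were also summed per gene and tested with edgeR's quasi-likelihood test after filterByExpr, which removed 0 of 5762 genes, so these values describe spliced reads of genes with introns and not total expression. Count minimums of 10 and 30 reads removed 0 introns, because the lowest sum over libraries was 240. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry (its directional test unless the mixed-direction one is named), and list members were counted on log2 fold changes. Genes overlapping on one strand, and near-identical copies, could share reads in the authors' counting and are uncertain.

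In the authors' ratios the replicate numbers pair the libraries. The correlation of each control library's deviations from its group mean with those of the same-numbered spk-1(RNAi) library was 0.88, 0.69, 0.71 and 0.75, in each case the highest for that control library. For control replicates 3 and 4 the margins were small, 0.71 against 0.70 and 0.75 against 0.69 for the other of spk-1(RNAi) replicates 3 and 4. Log2 CPM of control replicate 3 correlated slightly better with spk-1(RNAi) replicate 4 (0.978) than with replicate 3 (0.975). Pairing within replicates 3 and 4 is therefore only weakly borne out by the values. The fit with replicate number as a block lowered edgeR's common dispersion from 0.148 to 0.0288, and its value is given wherever it changed a call. The main fits, the 19 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named spk-1, ced-4, called sites whose groups did not overlap, the genes with the largest called changes, up to 4 members of each list with the smallest adjusted p and the 5 genes first in the exon-bin table. Other genes are said to be chosen after their values were seen.

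The tests were tried on simulated counts with the library sizes of the real ones. Apart from the set changes, both libraries of a pair were given the same mean, and the spread was the trend of the blocked fit. Pairing was thus built into the simulated counts, so the gain of the blocked fit there follows at least in part from this setting. Of genes changed 1.5-, 2- and 4-fold among 5762, the fit without block recovered 0%, 5.97% and 65.2%, with 0 unchanged genes called, and the blocked fit 56.7%, 76.1% and 100%, with 11 unchanged genes called. Of 40 sites changed by 20 percentage points among 150, the fits recovered 7.5% and 82.5%, and the blocked one called 2 unchanged sites. DESeq2 was not tried on simulated counts. Alternatives were DESeq2 size factors, DESeq2 1.42.0 (Wald and likelihood ratio tests), voom with diffSplice, other count minimums, each library left out in turn, introns compared within genes, and subsets of the pairs. Confidence intervals are exact binomial ones at 95% and cover counting error only, since the reads carry no molecular identifiers.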

Results

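Reads over introns were measured in whole adult Caenorhabditis elegans after feeding with either an empty vector or spk-1 double-stranded RNA. SPK-1 is the worm's SR protein kinase, an enzyme that phosphorylates the serine- and arginine-rich splicing factors. Each group held 4 libraries. The control libraries had 7938914, 1821717, 47299659 and 28177090 junction reads for replicates 1 to 4, and the spk-1(RNAi) libraries 4279845, 2660062, 40426751 and 29551827. Replicates 1 and 2 of both groups differed from replicates 3 and 4 more than the groups differed. Correlations of log2 CPM across genes, which are not independent replicates, were 0.86 to 0.91 between these sets of libraries and 0.97 to 0.99 among replicates 3 and 4. A split of the libraries into pairs 1 and 2 against pairs 3 and 4 called 2944 of 5762 genes in edgeR's quasi-likelihood test. Because the authors' ratios pair the libraries by replicate number, results with replicate number as a block are given beside those without it.

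The targeted gene was examined first. Reads over most spk-1 introns (B0464.5, chromosome III) were lower after spk-1(RNAi), and reads over the introns after exons 6 and 7 were far higher. The 8 other introns had mean junction reads 2.17- to 6.11-fold lower than in controls, and within a pair the ratio of spk-1(RNAi) to control at these introns ran from 0.0342 to 0.652. The lowest of these ratios, at the intron after exon 10 in pair 2, rests on 1 read against 25 in the control. Summed without the introns after exons 6 and 7, spk-1 had 423.6 ± 113.2 CPM in controls and 112.2 ± 56.56 CPM after spk-1(RNAi) (SD, n = 4), and was lower in 4 of 4 pairs, at ratios of 0.155, 0.239, 0.315 and 0.303. That sum fell by 2.01 on the log2 scale with the replicate block (SE 0.17, adjusted p = 0.000638 in edgeR), whereas without the block its log2 fold change was -1.91 (adjusted p = 1.0). This sum was defined after the introns' values were seen.

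Over the intron after exon 6 (9460140 to 9460981), mean CPM was 70.4 ± 29.3 in controls and 14778 ± 24794 after spk-1(RNAi), and over the intron after exon 7 (9461063 to 9461108) it was 50.01 ± 14.04 and 3556 ± 5429 (SD, n = 4). Both introns rose with the block in edgeR's test of 20324 introns, with log2 fold changes of 5.82 and 4.63 and adjusted p of 0.00163 and 0.00342. Among the 14 introns called in that blocked test, 9 were introns of spk-1, and without the block 0 introns were called, with 173 at an unadjusted p under 0.05. The 5 others lay in tos-1 (adjusted p = 0.00342) and nosr-1 (0.0044), both higher, and in acdh-1 (0.0288 and 0.0317) and folt-2 (0.0317), both lower. The spk-1 reads made up 0.0464% to 0.0628% of all junction reads in controls. After spk-1(RNAi) they made up 0.614% (95% exact interval 0.607% to 0.621%), 6.25% (6.23% to 6.28%), 0.178% (0.1771% to 0.1797%) and 0.277% (0.275% to 0.279%) in replicates 1 to 4. With all introns summed, spk-1 therefore had a log2 fold change of 5.06 (SE 1.13, adjusted p = 1.0), or 3.38 with the block (adjusted p = 0.192), and 2.68 without spk-1(RNAi) replicate 2 (adjusted p = 0.589). Double-stranded RNA made from spliced spk-1 sequence, if present in the worms or in the food, can itself add reads over introns, so reads at these introns cannot be assigned to the worm's own spk-1 RNA.

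**Figure D1:**
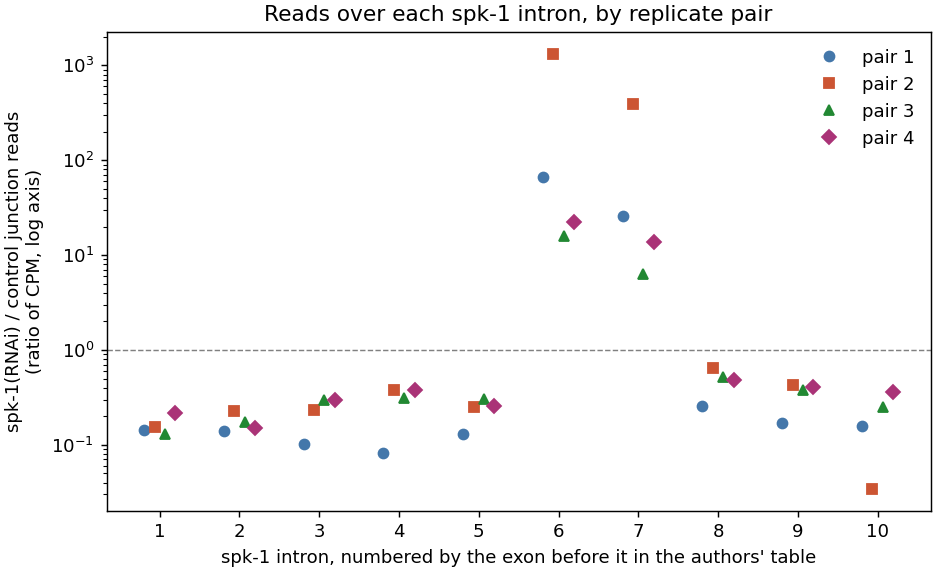
Ratio of spk-1(RNAi) to control junction CPM (log axis) at each of 10 spk-1 introns, numbered by the exon before them, with 1 point per replicate pair and a dashed line at a ratio of 1. The introns after exons 6 and 7 lie above 1 in all 4 pairs, and the 8 other introns lie between 0.0342 and 0.652. The lowest point rests on 1 read in spk-1(RNAi) replicate 2.

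The central comparison asked which alternative splice sites were used differently after spk-1(RNAi). An exon of tos-1 was skipped more often. In this gene (K07B1.6), used by splicing laboratories as a reporter of splicing factor activity, the 67 nt exon lies on chromosome V at 9343477 to 9343543. At its shared acceptor, the share of the exon-skipping intron rose from 22.5% ± 5.90 in controls to 52.6% ± 6.29 after spk-1(RNAi) (SD, n = 4), and at its shared donor from 21.7% ± 7.64 to 50.4% ± 2.78. The adjusted p was 0.0246 and 0.0274 in edgeR's test, and the share was higher in 4 of 4 pairs at each site. These were the only 2 of 150 shared sites called without the block, where 7 sites had an unadjusted p under 0.05. DESeq2's likelihood ratio test called 6 sites. Both tos-1 calls were lost when any control library or spk-1(RNAi) replicate 3 was left out (0 sites called), and without spk-1(RNAi) replicate 4 its acceptor site alone was called (1 site).

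With the replicate block, 8 sites in 5 genes were called, with 20 at an unadjusted p under 0.05. The largest change was in nosr-1 (Y17G7B.20), at a 57 nt exon on chromosome II (11978984 to 11979040). Skipping of that exon rose from 31.1% ± 6.52 to 68.2% ± 7.08 of reads at the acceptor and from 35.5% ± 2.14 to 68.2% ± 6.74 at the donor (SD, n = 4), with adjusted p of 4.21e-06 and 5.10e-05 in edgeR. For tos-1, the blocked adjusted p was 0.000153 and 0.00029. In alx-1 (R10E12.1), the worm counterpart of the endosomal sorting protein ALIX, the longer intron at a shared acceptor on chromosome III (9960699 to 9961459, against 9961359 to 9961459) rose from 38.7% ± 7.06 to 65.6% ± 14.1 (adjusted p = 0.000336). The homeobox gene ceh-38 (F22D3.1) behaved alike on chromosome II (6953988 to 6954336, against 6954208 to 6954336), from 36.3% ± 8.95 to 65.7% ± 9.56 (adjusted p = 0.0188), but was not called without pair 4 (adjusted p = 0.33). For nosr-1, alx-1 and ceh-38, the control and spk-1(RNAi) libraries did not overlap, and all 8 libraries had at least 52 reads at each of these sites.

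The fifth gene, mtm-3 (T24A11.1), of the myotubularin phosphatase family, was chosen after its values were seen because its groups overlapped. Its 335 nt exon (chromosome III, 3791262 to 3791596) was skipped in 33.5% ± 12.7 of reads at the acceptor in controls and in 55.4% ± 18.8 after spk-1(RNAi) (SD, n = 4), with 22.1% ± 4.45 and 44.5% ± 16.6 at the donor. The blocked adjusted p was 0.00187 and 0.00585, and the donor site was lost without pair 2 (adjusted p = 0.0571) or pair 3 (adjusted p = 0.0506). In pairs 3 and 4 alone, the deepest libraries, 6 sites were called without the block, in nosr-1, tos-1 and mtm-3, an alternative added after the data were seen. With pairs 2 and 3 alone, whose numbers stand in the headings themselves, the blocked fit also called 6 sites. That fit holds 4 libraries, leaves hardly any residual degrees of freedom and leans on spread borrowed across introns. Across all 150 sites, 9 sites (6%) had groups that did not overlap, where chance gives 2.86%.

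**Figure D2:**
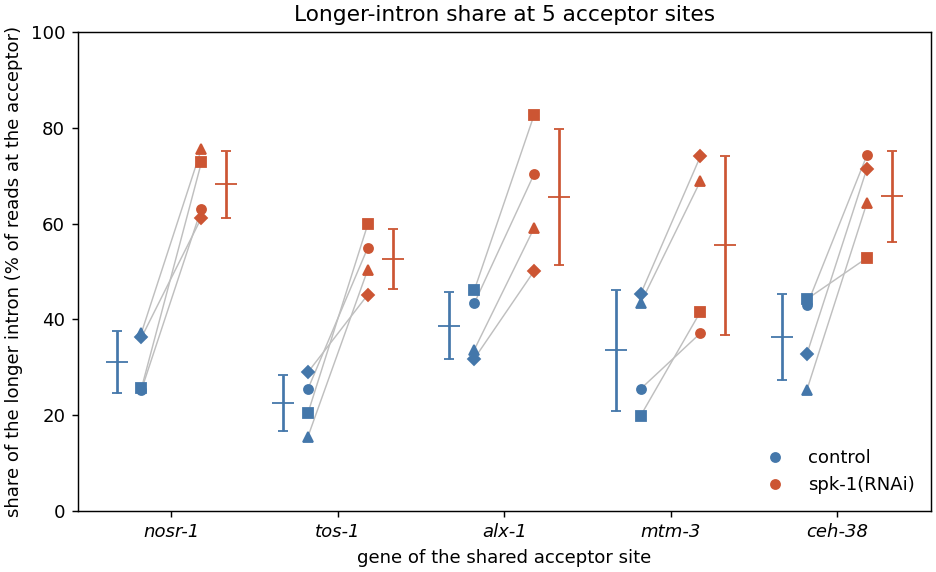
Share of the longer intron, in percent of reads at the shared acceptor, for nosr-1, tos-1, alx-1, mtm-3 and ceh-38, with 1 point per library (circle, square, triangle and diamond for replicates 1, 2, 3 and 4), grey lines joining the libraries of a pair and bars for the mean ± SD of 4 libraries. The share is higher after spk-1(RNAi) in 4 of 4 pairs in every gene, and the groups overlap only for mtm-3.

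The direction of these changes was also compared. At all called sites, reads moved toward the longer intron, in 2 of 2 sites without the block (exact 2-sided binomial p = 0.5, the smallest that 2 sites allow) and in 8 of 8 with it (exact 2-sided binomial p = 0.00781). The 8 sites are not independent, since they lie in 5 genes (5 of 5, exact p = 0.0625). Of the 8, 6 border the skipped exons of nosr-1, tos-1 and mtm-3. The other 2, in alx-1 and ceh-38, are shared acceptors counted as alternative donors because no skipped exon was listed there. The annotated transcripts at these sites were not checked, so the kind of event is uncertain. All 8 shifted by at least 10 percentage points. Over all tested sites, called or not, the longer intron had the higher mean share after spk-1(RNAi) at 20 of 22 skipped-exon sites, 17 of 27 alternative donors and 57 alternative acceptors (56.4% of them). Counted once per exon, mean skipping was higher for 10 of 11 skipped exons (exact 2-sided binomial p = 0.0117), and for 7 of the 8 in uncalled genes (exact p = 0.0703). Among the uncalled exons, that of ikke-1 was skipped in 50.3% ± 5.28 of control reads and 61.1% ± 7.04 after spk-1(RNAi), and that of hrpa-1, which encodes the hnRNP A1 protein, in 15.01% ± 8.56 and 19.98% ± 5.85 (SD, n = 4), both higher in 4 of 4 pairs. These genes were chosen after their values were seen.

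Introns were also compared with all other introns of their gene. In the 4370 genes with at least 2 introns, 1 gene was called without the block, spk-1, and 3 with it, spk-1, nosr-1 and tos-1 (10 and 249 genes at an unadjusted p under 0.05). No fixed list held more called sites than other genes past the threshold. Of the 9 lists with a gene tested for usage, 0 passed Fisher's exact test with or without the block, and the one with the lowest p held genes already reported as alternatively spliced, where tos-1 was called among 5 tested (exact 2-sided p = 0.0382, adjusted p = 0.344, with 96.6% of 10000 depth-matched random lists holding fewer, and with the block p = 0.179, adjusted p = 1.0 and 75.55%). Of the 8 other lists, the muscle, core spliceosome and RNAi machinery lists had 1 tested gene each, the germline, ribosomal and intestinal lists 3 each, the oocyte list 4 and the hnRNP-type list 5, and 0 of these genes was called. With the block, the skipped-exon acceptor of hrpa-1 passed when adjusted over the hnRNP-type list alone (adjusted p = 0.0368) and not over all sites (adjusted p = 0.0788). The donor of the same exon did not pass over the list alone (adjusted p = 0.174 in edgeR's blocked test). The cell death gene ced-4, whose splicing is known to depend on SPK-1, had 1 listed intron and thus no measurable choice of site. Its junction reads were 16.22 ± 1.55 CPM in controls and 11.8 ± 1.49 CPM after spk-1(RNAi), lower in 4 of 4 pairs (log2 fold change -0.45, SE 0.27, adjusted p = 1.0 in edgeR, n = 4).

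Junction reads per gene asked how gene expression changed. With 4 libraries per group, 0 of 5762 genes were called by edgeR without the block, with 54 at an unadjusted p under 0.05, and DESeq2's Wald test called 0, with 84. With the block edgeR again called 0 genes, but 553 had an unadjusted p under 0.05, 293 higher and 260 lower, and DESeq2's Wald test with the block called 51, of which 33 rose and 18 fell. In pairs 3 and 4 alone edgeR called 7 genes, and 213 with the block, and in pairs 1 and 2 alone 0 and 56. These subsets were added after the data were seen. Their blocked fits hold 4 libraries, leave hardly any residual degrees of freedom and lean on spread borrowed across genes. Other splits of these subsets were not run, so the counts of 213 and 56 do not show more changed genes than the full set.

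The genes closest to the threshold in edgeR's blocked test were F53H4.2, from 63.3 ± 27.2 to 116 ± 38.3 CPM (adjusted p = 0.0611), the cuticle collagen col-103, from 70.2 ± 25.7 to 133.2 ± 46.5 CPM (0.0737), and lias-1, which encodes lipoic acid synthase, from 62.3 ± 5.04 to 117.8 ± 33.7 CPM (0.0923), together with C08F11.12, from 58.5 ± 32.8 to 103.1 ± 40.3 CPM (0.0923; SD, n = 4 for each). Lower values were found for folt-2, a folate transporter gene, at 96.3 ± 30.1 and 40.1 ± 14.04 CPM (blocked log2 fold change -1.35, SE 0.26, adjusted p = 0.159) and for the acyl-CoA dehydrogenase gene acdh-1, at 389 ± 212 and 213.2 ± 175.5 CPM (-1.20, SE 0.22, 0.159). Further down stood T05E12.6, at 35.03 ± 22.6 and 19.6 ± 15.9 CPM, hphd-1, at 128.7 ± 52.5 and 77.7 ± 44.3 CPM, and pud-4, at 81.3 ± 71.8 and 134 ± 82.0 CPM, the last from a family of near-identical genes whose reads the counting could share. Each of these 9 genes moved the same way in 4 of 4 pairs and was among the 51 of DESeq2's blocked test. The genes were picked for small blocked p-values, so the agreement between pairs follows at least in part from that choice. DESeq2's blocked test used the same reads and pairs, so neither is separate evidence. All but col-103 and acdh-1 were chosen after their values were seen.

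Gene lists fixed by tissue and function were compared next. The lists were measured unevenly, in 22 of 116 collagen and hypodermis genes, 27 of 52 muscle, 11 of 49 detoxification, 4 of 66 neuronal and 1 of 67 sperm genes. By contrast 41 of 44 germline stem cell and P granule, 39 of 43 meiosis and 49 of 49 oocyte genes were measured. Cuticle collagens had the highest median, with 20 of 22 measured genes higher after spk-1(RNAi) (median log2 fold change 0.50, camera adjusted p = 3.40e-11 at a preset correlation). The list was not called with an estimated correlation (adjusted p = 0.584) or with fry (adjusted p = 0.867). In edgeR's blocked test 0 genes of the list passed over all genes and 14 passed when adjusted over the list alone, all higher, among them col-103 (blocked log2 fold change 0.90, SE 0.13), col-93 (0.79, SE 0.17) and col-98 (0.97, SE 0.21). DESeq2's blocked Wald test called these 3 and col-94 over all genes (4 of the list). The collagen col-160 stood at 355 ± 67.6 and 591.7 ± 177.3 CPM (SD, n = 4). Body-wall and pharyngeal muscle genes were higher in 23 of 27 (median 0.18, camera adjusted p = 0.00286), a call likewise lost with an estimated correlation (adjusted p = 0.618) and with fry (adjusted p = 0.905), and 0 of the 27 passed edgeR's blocked test over all genes or over the list alone, or DESeq2's blocked test over all genes. Troponin C pat-10 stood at 1501 ± 311 and 2070 ± 342 CPM and the type IV collagen let-2 at 304 ± 180 and 369.4 ± 147.4 CPM. The muscle median within pairs was 0.14, 0.97, -0.03 and 0.08 for pairs 1 to 4, highest in pair 2, and the collagen median was 0.58, 1.32, 0.21 and 0.27. Both lists also differed between the library sets, with 17 of 27 muscle genes and 7 of 22 collagens called higher in pairs 3 and 4 than in pairs 1 and 2.

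With the replicate block, camera called 7 lists, and 0 were called with an estimated correlation (adjusted p of 0.658 to 0.69 for these 7) or by fry's directional test. Passes over a list alone are from edgeR's blocked test, and each gene named here with such a pass, none of them called over all genes in edgeR, was called over all genes by DESeq2's blocked Wald test. Besides collagens and muscle, 3 lists were called higher. In the yolk and intestine list, 28 of 36 genes were higher (camera adjusted p = 0.0313) and 2 passed when adjusted over the list alone, the desaturase gene fat-6, higher (log2 fold change 0.54, SE 0.13), and acdh-1, lower, while far-2 (0.37) and fat-2 (0.36) did not pass. The list medians were 0.043, 0.51, -0.023 and 0.056 in pairs 1 to 4. In the detoxification list 9 of 11 were higher (0.0397), and the glutathione S-transferase gene gst-10, from 16.22 ± 2.11 to 29.5 ± 9.26 CPM, passed over the list alone, unlike the cytochrome P450 gene cyp-35A2 (0.48, SE 0.15). In the innate immunity list 13 of 17 were higher (0.0313), with 0 passing over the list, including nlp-31 (0.59), zip-2 (0.45) and clec-85 (-0.41), and its medians were -0.04, 0.69, -0.07 and 0.25, above 0 in 2 of 4 pairs. The detoxification medians were 0.015, 0.42, 0.12 and 0.22.

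The 2 lists called lower with the block held RNA-binding and meiotic genes. Among hnRNP-type and tissue splicing regulators, 18 of 28 were lower (camera adjusted p = 0.0313), and 2 passed over the list alone in edgeR and over all genes in DESeq2's blocked test, the splicing regulator rbm-5, from 201 ± 23.1 to 132 ± 32.7 CPM (log2 fold change -0.62, SE 0.12), and sqd-1, at 629 ± 395 and 448 ± 273 CPM (-0.45, SE 0.12). The hnRNP K gene hrpk-1 (-0.29) did not. The list medians were -0.14, 0.016, -0.16 and 0.00088 in pairs 1 to 4, below 0 in 2 of 4 pairs. Among meiosis genes 24 of 39 were lower (0.0397), and cosa-1, a crossover factor, passed both in the same way (-0.68, SE 0.15), while spo-11 (-0.39), which makes meiotic double-strand breaks, did not. The meiosis medians were -0.0038, -0.25, -0.096 and 0.0085.

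**Figure D3:**
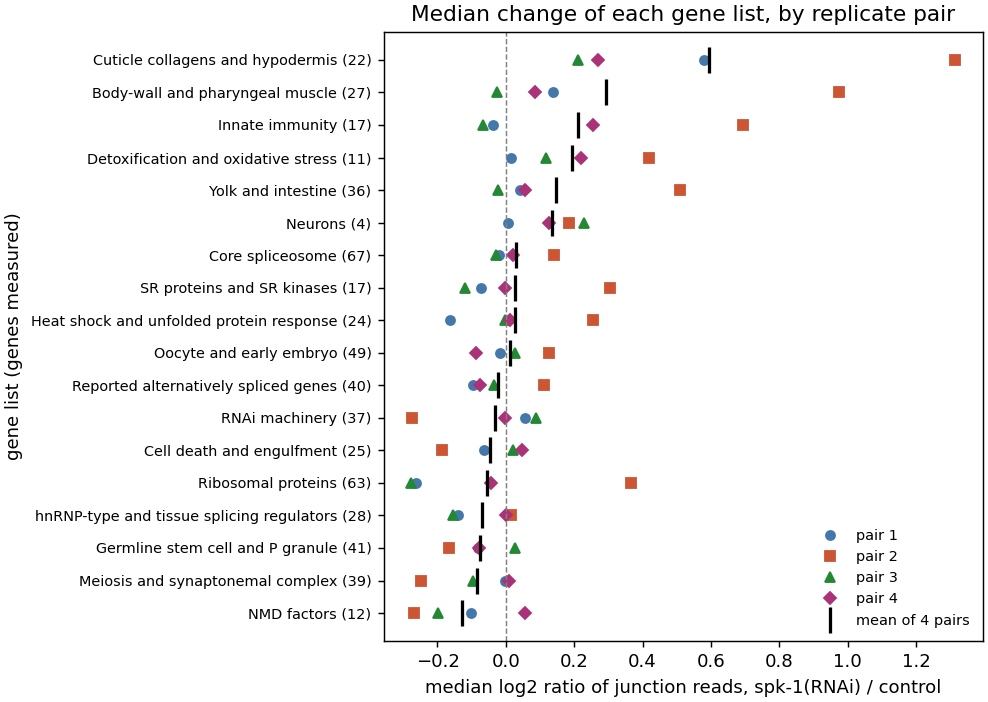
Median log2 ratio of junction reads, spk-1(RNAi) over control, for 18 gene lists (number of measured genes in brackets), with 1 point per replicate pair and a bar for the mean of 4 pairs. The collagen median is above 0 in 4 of 4 pairs, between 0.21 and 1.32, and pair 2 stands apart from the other pairs in several lists.

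Camera called none of the remaining lists, with or without the block. Among them were the lists of splicing factors. Of 17 SR proteins and SR kinases 6 were higher and 11 lower (median -0.05, though camera's direction was up), including rsp-5 (-0.41) and rsp-7 (0.21), and only spk-1 passed over the list alone, on the sum of all its introns, which counts among the 6 higher and is lower without the introns after exons 6 and 7 (-1.91). Of 67 genes in the core spliceosome list 37 were higher (median 0.01; both counts include the Argonaute gene ppw-2, which stands in this list by mistake), with rnp-2 at 0.52 and plrg-1 at 0.46. In the cell death list 17 of 25 were lower (median -0.06), the apoptosis factor wah-1 at -0.48 and the nuclease gene nuc-1 at 0.36. Germline stem cell and P granule genes were lower in 26 of 41 (median -0.06), glh-2 at -0.32 and fbf-1 at -0.46, and oocyte and early embryo genes in 27 of 49 (median -0.02), the polarity genes par-2 at -0.30 and par-4 at -0.36. Nonsense-mediated decay factors were lower in 9 of 12 (median -0.12), smg-3 at -0.20 and smgl-2 at -0.29. RNAi machinery genes were lower in 23 of 37 (median -0.04), with the Argonaute gene ppw-2 at 0.39 and eri-1 at -0.36. Genes reported as alternatively spliced were lower in 26 of 40 (median -0.04), pqn-70 at -0.49 and hum-2 at -0.28. Heat shock and unfolded protein response genes split 12 against 12, hsp-25 at 0.41 and dnj-12 at -0.27. Ribosomal protein genes were lower in 53 of 63 (median -0.09), rpl-10a at -0.25 and rpl-34 at -0.21, although their median in pair 2 was 0.36. Of 4 neuronal genes 3 were higher, tdc-1 at 0.20, and with the block fry's mixed-direction test called this list (adjusted p = 0.00869), whereas spe-39, the single measured sperm gene, too few for a list test, stood at 0.12. All values here are log2 fold changes without the block, with 4 libraries per group.

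The authors' own comparisons were described as deposited. In the authors' deposited table of exon bins, spk-1 was the only gene with bins past an adjusted p of 0.05. That table held 176761 bins, 63977 of them without a p, and the 4 bins past 0.05, at 0.01 and at 0.1 alike, were bins 8 to 11 of the 19 bins of spk-1, with adjusted p from 1.79e-08 to 0.000413. Bins 8, 10 and 11 also had the highest normalized means of the gene in the authors' deposited table (241900, 93040 and 59120). The other 4 genes of the 5 with the lowest p in the authors' deposited table were T21C9.4+T21C9.1, with the lowest adjusted p outside spk-1 (0.124), C35D10.12 (0.868), the SR protein gene rsp-6 (0.868) and F22E5.13 (0.894). None of the 5 genes called here with the block had a bin past 0.05 in the authors' deposited table, where 1112 bins had an unadjusted p under 0.05.

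The authors' deposited junction tables listed 258 introns in 236 genes at p under 0.01, of which 202 were lower and 56 higher after spk-1(RNAi), each in 4 of 4 pairs. With 4 ratios per intron, this cut can only be passed when all 4 lie in the same direction. The agreement between pairs therefore follows from the listing and is no separate evidence. Without any change, 203 of the 20349 introns would pass by chance, and 0 passed after Benjamini-Hochberg adjustment of the authors' p-values (lowest adjusted p = 0.11, with 1223 introns at an unadjusted p under 0.05 in the authors' deposited table). Of these introns 8 belong to spk-1, the 2 with the lowest of its p-values being those after exons 1 and 2, with mean ratios of 0.155 and 0.164 in the authors' deposited table. Among the genes with a shared site, 18 had an intron in the shorter table, and 3 of the 5 genes called with the block were among them (Fisher's exact 2-sided p = 0.0185). Both lists come from the same libraries, so this overlap is not independent. For ced-4 the authors' deposited table gave a mean ratio of 0.719 and p = 0.0476 for its intron.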

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

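The tests on spk-1, on the direction of called sites and on splits of the libraries were chosen after the results were seen, whereas those on the authors' shorter intron table were written before. Of 140 groups of 4 libraries examined for a library far from the others, 9 held one, where chance gives about 7 (1 in 20).

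In spk-1, the introns after exons 6 and 7 had many more reads after RNAi while its other introns had fewer. A shift of the worm's own transcript toward these introns is argued against by their level, since the lowest spk-1(RNAi) library at either (376 CPM) was 2.52 times the highest control value of any spk-1 intron (149.5 CPM). Reads made from the RNAi trigger stay open as a candidate explanation. They would add to the trigger's own introns alone, but that 0 of the 8 other introns had a higher mean is part of the pattern itself and decides nothing, and the trigger's sequence is not given in the sources used here. Whether such reads would come from the worm or from bacteria was not tested. A lower level of the endogenous transcript, which is what the treatment aims at, remains a hypothesis for the other introns.

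Replicate 2 of spk-1(RNAi) stood far above the other 3 in these reads. Reads over all spk-1 introns made up 6.25% of its junction reads (95% exact interval 6.23% to 6.28%), against 0.178% to 0.614% in the other libraries of the group. Its intron after exon 6 had 51949 CPM, against 1505 to 3473, and its intron after exon 7 had 11676 CPM, against 376 to 1361. In controls, replicate 2 was low at the spk-1 intron after exon 5, with 38.5 CPM against 49.5 to 49.8. Single libraries also stood apart for cosa-1 (control replicate 2, 122.9 CPM against 29.8 to 44.9) and C08F11.12 (control replicate 1, 107.4 CPM against 37.05 to 46.3). The same held for wah-1 (spk-1(RNAi) replicate 1, 28.4 CPM against 41.9 to 43.2), hum-2 (spk-1(RNAi) replicate 2, 139.4 CPM against 213 to 224) and rpl-34 (spk-1(RNAi) replicate 1, 1040 CPM against 1365 to 1426).

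All 8 sites called with the replicate block, in nosr-1, tos-1, mtm-3, alx-1 and ceh-38, moved toward the longer intron. In both pair 3 and pair 4, 8 of 8 sites moved by at least 10 points. These pairs were part of the fit that called the sites, so this does not decide on the shallow libraries of pairs 1 and 2. In pairs 3 and 4 alone, without the block, 6 sites in nosr-1, tos-1 and mtm-3 were called, all toward the longer intron. For these genes the shallow libraries are argued against as the whole cause, whereas for alx-1 and ceh-38 they stay open. A general shift of reads to longer introns stays open. Over all 150 sites, 94 (62.7%) had a higher mean share of the longer intron (exact 2-sided binomial p = 0.00241). These sites lie in 132 genes, and each skipped exon counts at both its donor and its acceptor. They are thus not independent, and this p may be too small. The lower share among uncalled alternative donor and acceptor sites (57.1%) leaves out the called sites and all skipped exons. The median change was 1.07 points over all 150 sites and 0.56 points over these uncalled ones. Calling favours large changes, so the larger shifts at the 8 called sites do not decide. For skipped exons outside the called genes, chance direction of single exons stays open (7 of 8 toward skipping, exact 2-sided binomial p = 0.0703). Lower exon inclusion through reduced SPK-1 activity stays among the open explanations, and sites whose short or long intron was rare in controls were not listed.

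More introns were lower than higher in the authors' shorter table, 202 against 56. Unlisted introns were also more often lower (56.3%), and the median log2 of the authors' ratio over all introns was -0.043. An even split is therefore not the base for these shares. With ratios centred on the median of each pair, 75.7% of introns at p under 0.01 were lower. Listing introns by their reads in the control libraries stays open as a cause. Of the 45 listed introns with at least 100 reads in every control library, 80% were lower, past the bound set against this cause. That check again chose introns by control reads alone, so it keeps the selection in question and cannot decide. With the test run on the logarithm of the ratio, 63.4% of introns at p under 0.01 were lower, against 56.3% of unlisted introns. The 63.4% lies between the bounds set for and against a role of the scale. The part of the scale therefore cannot be told apart from the rest. Whether a change in the level of the whole gene accounts for the excess of lower introns cannot be decided. In 76.2% of 214 genes the other introns moved in the direction of the listed one. For random genes this was 54.3% on average and 67.8% at most in 10000 draws. The share was 78.2% where the listed intron was lower and 69.4% where it was higher. Introns of a gene thus moved together in both directions, which does not tell why more were lower. The other introns moved less than the listed ones, with median log2 ratios of -0.17 against -0.49 where the listed intron was lower and 0.095 against 0.36 where it was higher.

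Other splits of the 8 libraries were compared with the real one. Without the block, 2 of 35 splits called as many sites as the real one (2), so chance cannot be excluded. The highest other split called 8 sites and parts pairs 1 and 2 from pairs 3 and 4, a structure of the samples rather than of the treatment, and with pairs as a block the real split called 8. For lists, 34 of 35 splits called at least the 2 of the real split (highest other 10), so chance is not excluded there either. For genes the real split called 0, so that 35 of 35 splits called as many was fixed beforehand and decides nothing (highest other 2944, the split of pairs 1 and 2 from pairs 3 and 4). With the block, only 8 splits part every pair, too few for a share under 0.05. The real split called 8 sites (highest other 0) and had 553 genes at an unadjusted p under 0.05 (highest other 365), as 1 of 8 splits in each case.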

How the results depend on the processing

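Subsets of pairs, blocked fits with a library pair left out, blocked fits by other tools and the changes to spk-1 introns and the authors' intron test were chosen after the data were seen. Of 917 alternative values, 824 kept their direction and their side of the threshold or, for counts, lay within 1.5 times the reported count, 36 were weaker (a call lost or a lower count), 55 stronger and 2 reversed, and among 50 named genes and 8 named sites 0 of 816 values reversed. The reversed values are the spk-1 sum without the introns after exons 6 and 7 (log2 fold change -1.91, or -2.01 with the block), by construction.

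Sites called (2) became 8 with the replicate block, 6 with DESeq2's likelihood ratio test and 1 gene with introns compared within genes. Leaving out 1 library gave 0 to 3 sites, and leaving out a pair under the block 7 to 8. Pairs 3 and 4 gave 6 (7 with the block), pairs 1 and 2 gave 0 (5 with the block), and pairs 2 and 3 with the block gave 6. The block lowers the residual spread, and subsets hold fewer samples. Blocked fits of 2 pairs therefore lean mostly on spread borrowed across introns or genes. For other differences the cause was not tested. Called sites moved by at least 10 points (2) became 8 with the block and 0 to 3 without 1 library. Called sites moved toward the longer intron (2) became 8 with the block (exact p = 0.00781) and 1 to 3 without 1 library, with no value where no site was called.

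Genes called (0 in edgeR, 54 at an unadjusted p under 0.05, 0 by DESeq2) became 51 in DESeq2's Wald test with the block, 7 and 213 in pairs 3 and 4 without and with the block, 56 in pairs 1 and 2 with it, and 0 to 7 under the block with a pair left out. Gene lists called (2) became 7 with the block, 2 to 7 without 1 library, 0 with an estimated correlation, 0 by fry's directional test, and under the block 0 by either. The authors' 258 introns became 26 at p under 0.001 and 45 with at least 100 reads in every control library, both smaller by construction. TMM and DESeq2 size factors gave the same counts of sites and genes. The count minimums removed no intron and say nothing about stability. Depth limits the precision of shares at single sites in control replicate 2, which had a median of 41 reads per intron, though leaving it out gave 0 sites and not more.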

Other observations

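The tests on X-linked genes and on tissue lists were chosen after the results were seen, and the test on propionate breakdown was written before the other genes of that pathway were looked at.

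Genes on the X chromosome had slightly more junction reads after spk-1(RNAi) relative to autosomal genes. With the replicate block the median log2 fold change was 0.12 for 394 X-linked genes and 0.00 for 5368 autosomal ones, and X-linked genes had the higher median in 4 of 4 pairs, by 0.02, 0.19, 0.10 and 0.11. Few X-linked genes act in the germline, and only 2 of the measured genes in the germline, meiosis and oocyte lists are X-linked. The median of the muscle, intestine and neuron lists (67 genes) exceeded that of these germline genes in 4 of 4 pairs, by 0.10, 0.72, 0.01 and 0.15, a mean of 0.24 with an SD of 0.32 over pairs. A lower share of germline RNA in the spk-1(RNAi) worms could give this order, but finding both medians in that order in 4 of 4 pairs repeats the observation that prompted the test, so the explanation stays open. The shifts are small and largest in pair 2, and germline size was not measured here. The somatic lists were also measured less completely than the germline ones, the neuron list in 4 of 66 genes.

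The collagen median exceeded that of the muscle, intestine and neuron lists in 4 of 4 pairs, by 0.49, 0.72, 0.20 and 0.19, a mean of 0.40 with an SD of 0.26. The collagen list was taken up because it had the highest median, so this difference does not decide whether a lower share of germline RNA could account for the collagen values. Collagen levels also change with age in young adults, and a difference in stage between the groups was not tested and stays open.

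The acyl-CoA dehydrogenase gene acdh-1 and hphd-1, lower in 4 of 4 pairs with blocked log2 fold changes of -1.20 and -0.86, both act in the breakdown of propionate. A lower level of the propionate breakdown pathway as a whole could account for this. The other measured genes had blocked values of -0.25 for hach-1 (lower in 4 of 4 pairs), -0.09 for alh-8 and -0.06 for ech-6. Their median of -0.092 misses the bound of -0.3 set for the pathway and meets the bound of -0.1 or higher set against it, but by less than their errors (SE of 0.10 to 0.16), so the explanation cannot be told apart from a change of single genes.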
